A study of Arabidopsis thaliana with 4 samples.

How the data were processed

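Small RNA libraries of 4 groups of Arabidopsis thaliana seedlings, C24, Ler and the F1 hybrids C24xLer and LerxC24, were analysed from the alignments the authors deposited, with 1 library per group. Per the labels, seedlings were collected at 14 to 15 days from plants grown at 23 C with 16 h of light and 8 h of dark, pooled, and total RNA was extracted and made into small RNA libraries. The order of the parents in the cross labels is not explained there. Reads had been aligned with novoalign 2.05.02MT after removal of the 3' adapter, per the file headers; the version is 2.10 per the submitters' processing notes. The genome build of these alignments is not given in the sources used here. Each line of the deposited alignments is a read with its sequence, its status (unique, repeat, unmatched, or filtered for quality) and, for unique reads, its position. The alignment score and mapping quality of each read, and the score column of the deposited lists of uniquely mapped reads, are the aligner's own values, per the file headers, and were not used as measurements. The lists of uniquely mapped reads held as many lines as the alignments held unique reads in all 4 libraries.

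Read counts were made here by counting lines. The aligner's quality filter had removed 8.58% of reads in C24, 12.3% in Ler, 24.4% in C24xLer and 21.8% in LerxC24, and 12.6%, 12.2%, 10.3% and 9.95% were unmatched. All unique and repeat reads of 18 to 30 nt formed the library total, and levels are counts divided by it. Of the uniquely mapped reads, 29.6%, 28.4%, 26.7% and 26.5% carried at least 1 mismatch in the same order of libraries, which matters because C24 and Ler differ in sequence from the reference. Because positions could not be tied to a build, each distinct sequence was placed again on TAIR10.1 with bwa 0.7.19, allowing up to 2 mismatches and no gap, and samtools 1.23.1. Of the authors' unique reads 98.5%, 98.6%, 98.3% and 98.8% were placed at a unique position. Gene annotation was that of the same assembly. It has no separate transposon annotation, so pseudogenes and transposon genes stand for transposons. Counting, intervals and figures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

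Comparisons, thresholds, gene lists, the naming rule and most alternatives were fixed before the data were examined, except where a choice is said to follow from the data. The 4 comparisons were Ler against C24, each hybrid against the mean of the parental levels (mid-parent), and LerxC24 against C24xLer. With 1 library per group a comparison is of libraries, not of conditions, and no p-value was computed. Each ratio carries an exact conditional binomial (Clopper-Pearson) interval at 95%, which covers counting error only; the mid-parent value enters as a count with the same mean and counting variance. A ratio against 0 reads is a bound computed with 3 counts in that library.

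Loci were built from uniquely placed 24-nt reads of the 4 libraries pooled, in 500-bp windows by read midpoint; windows with at least 40 reads were kept and touching windows merged, which gave 7526 loci with a median length of 500 bp and a longest of 13000 bp. A locus differed between parents, or between reciprocal hybrids, at 2-fold or more with an interval excluding equality, and from mid-parent at 1.5-fold or more. The number expected from counting error is the mean of 20 simulations with Poisson counts at equal levels, or at the mid-parent level for hybrids. The rule for named loci took, per comparison, the 8 higher and 8 lower loci of at least 200 pooled reads with the interval bound nearest to equality farthest from it, on the same side of mid-parent in both hybrids where a hybrid was compared with its parents. A locus carries the name of the gene it overlaps most, or of the nearest gene within 1 kb. A part of a gene is named by where most reads of the locus lie, by read midpoint, and a locus is put at the edge of a gene where its window overlaps the gene but at most 3.27% of its reads lie inside. Locus coordinates are those of the windows. The pericentromere was taken as 2.5 Mb on each side of the centromere.

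MiRNAs were counted as reads identical to 73 listed mature sequences in 6 groups, all of which lay in the annotated locus of their name; 42 reached 100 pooled reads, and a change of 1.5-fold with an interval excluding equality was called. At most the 12 with intervals farthest from equality are named per comparison. Reads of sequences shared by several loci cannot be assigned to a single locus, and the position given is that of the named locus. The 7 gene lists were trans-acting siRNA genes (8), PPR genes of the chromosome 1 clusters (14), auxin receptor genes (4), genes of RNA-directed DNA methylation and silencing (18), known silenced or siRNA-associated genes (10), circadian clock genes (8) and the RPP4 and RPP5 resistance gene cluster (4). Uniquely placed 21-nt reads over the gene and 24-nt reads over the gene with 1 kb on each side were counted, members with at least 40 pooled reads were measured, and 1.5-fold was the threshold in all comparisons. List medians were set against 10000 random lists of equal size and similar level, after adding 0.5 to each count. Members of the PPR clusters are similar in sequence, so reads shared between them are left out of these counts.

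Diagnostic sites had at least 5 reads in each parent, at least 90% of a base in the one library and at most 10% in the other. Hybrid reads over them were assigned by base, apart for sites where C24 or Ler carried the reference base, because mismatched reads align less well, and the mean of both is given. Structural RNA fragments were reads whose first 18 bases lie in annotated ribosomal, transfer, small nuclear or small nucleolar RNA. Alternatives covered the scaling (uniquely mapped reads, listed miRNAs, reads without structural and organelle RNA, reads of 20 to 22 nt), distinct sequences, mismatches, window size, depth minimum, size class and fold threshold. Scaling to structural fragments of the same length or to uniquely placed 24-nt reads, and 23- to 25-nt reads together, were added after the data were seen. The scaling to uniquely placed 24-nt reads takes out the overall 24-nt level, because 79.8% to 82.1% of these reads lay in the loci. Medians near mid-parent follow largely from its construction, so it compares loci only with each other. Leaving out a library was not possible, since each group has 1.

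The procedure was tested on simulated data, with 200 of the 7526 loci changed by a known fold. Changes of 2-fold, which equals the threshold between parents and between hybrids, were recovered at 47.0% of loci for Ler against C24 and for the reciprocal hybrids, and at 76.5% and 71.0% for C24xLer and LerxC24 against mid-parent. Changes of 3-fold were recovered at 87.5%, 92.0%, 90.0% and 87.5% for the 4 comparisons in the order given above, and 0 loci were called in the wrong direction. Intervals covered the true ratio at between 95.9% and 96.4% of loci. All 300 planted diagnostic sites were found, and a planted share of 60% was returned as 60.0%.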

Results

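Small RNAs were sequenced from whole seedlings of Arabidopsis thaliana, 2 weeks old, of the ecotypes C24 and Landsberg erecta (Ler) and of their reciprocal F1 hybrids, labelled C24xLer and LerxC24. The labels give 1 library for each of these 4 groups, made from pooled seedlings, so no difference reported here has a replicate check and no test between conditions was made. The deposited alignments held 4322617 reads for C24, 5110290 for Ler, 5271360 for C24xLer and 5448908 for LerxC24. Of these, 3402834, 3846873, 3442802 and 3714861 reads of 18 to 30 nt matched the genome and served as the library totals. Values in brackets after a ratio are exact 95% counting intervals, which cover counting error only, because reads from amplified libraries are not independent molecules. Each group is 1 library, so differences of library preparation or sequencing lane cannot be told apart from those between groups. Coordinates are those of a match of each read to the TAIR10.1 genome, and a read count of 0 at a locus refers to reads within 2 mismatches of that reference.

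The length classes of small RNA differed between the ecotypes and between parents and hybrids. The 24-nt class, which holds most heterochromatic siRNAs, made up 33.4% of genome-matched reads in C24 and 40.4% in Ler, but 29.5% in C24xLer and 25.3% in LerxC24. The 21-nt class, which holds many miRNAs and trans-acting siRNAs, made up 19.3% in C24, 13.6% in Ler, 21.3% in C24xLer and 21.5% in LerxC24. Against the mean of the parents, the 24-nt level was 0.800 (0.798 to 0.802) in C24xLer and 0.685 (0.683 to 0.686) in LerxC24, and the 21-nt level was 1.29 (1.29 to 1.3) and 1.31 (1.3 to 1.31). Ler had 1.21 times the 24-nt level of C24, and 0.704 times its 21-nt level (0.702 to 0.707). LerxC24 had 0.856 times the 24-nt level of C24xLer (0.854 to 0.859) and 1.01 times its 21-nt level. The sum of the listed mature miRNAs was 1.34 and 1.18 times the mid-parent value in C24xLer and LerxC24. Most of these miRNA reads came from few sequences. In C24, miR156a gave 255198, miR157a 181013 and miR158a 74651 of 618864 reads. In Ler they gave 235780, 138254 and 156485 of 622380. The counted sequences of miR156a and miR158a are shorter than 21 nt, so the 21-nt level does not stand for the miRNA level. Relative to miRNA reads, the 21-nt level of C24xLer was 0.974 of the mid-parent value, on the other side of it.

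**Figure D1:**
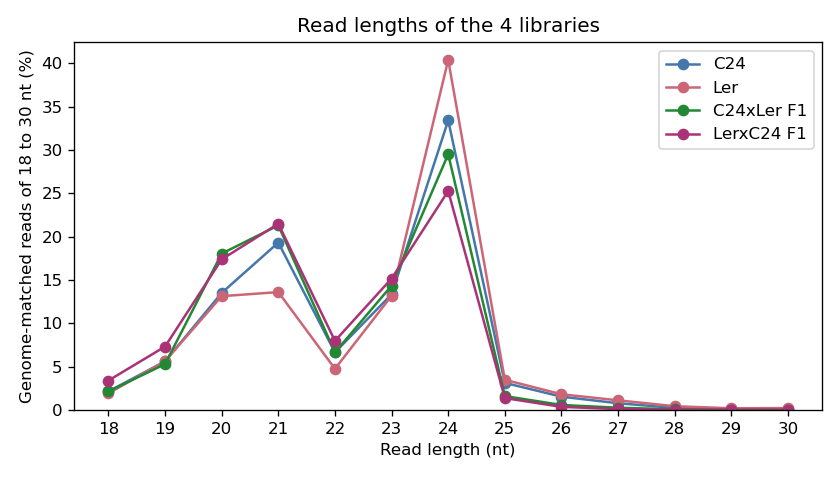
Percent of genome-matched reads at each read length from 18 to 30 nt, with 1 line per library. The 24-nt point stands at 40.4% in Ler, 33.4% in C24, 29.5% in C24xLer and 25.3% in LerxC24.

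Fragments of structural RNA also had fewer 24-nt reads per 21-nt read in the hybrids than in the parents. Among ribosomal RNA fragments this ratio was 1.14 in C24, 1.98 in Ler, 0.830 in C24xLer and 0.843 in LerxC24. Transfer RNA fragments gave 1.56, 2.62, 0.879 and 0.367 in the same order, and chloroplast reads gave 1.56, 1.92, 1.01 and 0.609. For small nuclear and nucleolar RNA the values were 0.460, 0.690, 0.318 and 0.238, and for mitochondrial reads 0.713, 1.08, 0.563 and 0.444. For ribosomal, transfer, small nuclear and nucleolar RNA together, the ratio was 0.491 (0.483 to 0.5) of the mid-parent ratio in C24xLer and 0.410 (0.404 to 0.416) in LerxC24. Over all genome-matched reads the corresponding values were 0.590 and 0.501. Scaled to structural RNA fragments of 24 nt, a setting chosen after the data were seen, the 24-nt level was 1.45 times the mid-parent value in C24xLer and 0.829 in LerxC24. Structural RNA made up 15.2%, 13.8%, 10.6% and 16.5% of genome-matched reads in C24, Ler, C24xLer and LerxC24. Scaling to its fragments therefore also carries the amount of structural RNA. As a share of structural fragments, those of 24 nt were at 0.751 and 0.724 of the mid-parent share in C24xLer and LerxC24. The same scaling at 21 nt put the 21-nt level of LerxC24 at 0.680 of the mid-parent value and 0.564 of C24xLer, and that of Ler at 1.33 times C24, each on the other side of equality.

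**Figure D2:**
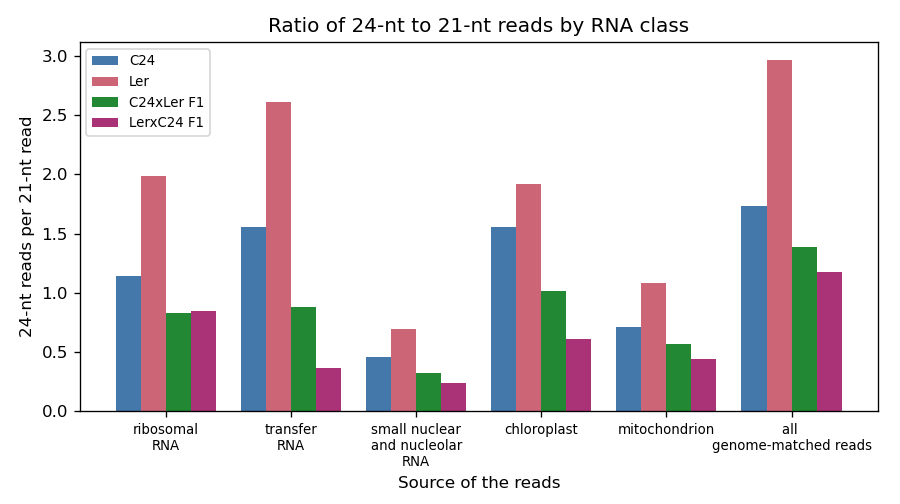
Number of 24-nt reads per 21-nt read for each source of RNA (bars, 1 per library; the axis starts at 0). For each of the 5 structural or organelle sources and for all reads, both hybrids lie below both parents; for ribosomal RNA the values are 1.14 in C24, 1.98 in Ler, 0.830 in C24xLer and 0.843 in LerxC24.

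The parental comparison asked how far the siRNA populations of the ecotypes differ before any cross. Ler had more 24-nt siRNA than C24 in every annotated class, led by pseudogenes and transposon genes at 1.41 times the C24 level. The other classes stood at 1.31 in protein-coding gene bodies, 1.21 in the 1 kb upstream of genes, 1.24 in the 1 kb downstream and 1.22 elsewhere. Individual loci differed far more than these sums, up to the complete absence of counted reads in one ecotype. Of 7526 loci with 24-nt siRNAs, 2316 were at least 2-fold higher in Ler and 1359 at least 2-fold lower, where counting error alone gave 54.3 and 48.8 in simulated libraries. Relative to uniquely placed 24-nt reads the split was 1912 higher and 1726 lower. This scaling was chosen after the data were seen and takes out the overall 24-nt level. In Ler, the 24-nt to 21-nt ratio of structural fragments was also above that of C24 in every class of RNA given above.

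Loci with differences between the ecotypes were spread over genes and the space between them. Of the 1665 loci overlapping protein-coding genes 53.4% differed, against 46.0% of the 1522 loci overlapping pseudogenes or transposon genes, 46.8% of the 395 loci overlapping non-coding RNA genes, 48.7% of the 2747 loci within 1 kb of a gene and 47.0% of the 1197 loci farther away. Loci on chromosome arms differed in 52.7% of 4248 cases and pericentromeric loci in 43.9% of 3278. The loci described next are the 8 higher and 8 lower loci whose counting intervals lay farthest from equality. In an intergenic region of chromosome 1 (9202501 to 9203000), 2800 bp from the nearest gene, Ler had 2631 reads and C24 had 0, at least 776-fold higher in Ler. A locus overlapping the pseudogene AT3G43730 (chromosome 3, 15635001 to 15640500), with 49.7% of its reads in it, had 2 reads in C24 and 2635 in Ler, a ratio of 1165 (322 to 9628). GH9B11 (AT2G44560) and GH9B12 (AT2G44570), neighbouring glycosyl hydrolase genes, had siRNAs over coding sequence in Ler. They were at least 296-fold higher at GH9B11 (chromosome 2, 18393001 to 18393500; 0 reads in C24) and 908 times the C24 level at GH9B12 (18396001 to 18396500; 163 to 35882). A locus at the edge of AT3G16850 (chromosome 3, 5748001 to 5748500), with no read midpoint inside the gene, had 1 read in C24 and 1360 in Ler, and a locus 106 bp downstream of the glycosyltransferase gene UGT71B8 (AT3G21800; chromosome 3, 7679501 to 7680000) was at least 203-fold higher in Ler. AT3G50540 (chromosome 3, 18758001 to 18758500, coding sequence) and AT1G49032 (chromosome 1, 18138001 to 18138500, coding sequence) were at least 209-fold and at least 197-fold higher in Ler. At these 2 loci 92.7% and 91.4% of the reads carried a mismatch to the reference, and without such reads the folds were at least 14.7 and at least 19.5.

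Among the loci lower in Ler, a locus 1 bp upstream of AT3G45750 (chromosome 3, 16798001 to 16798500) had 345 reads in C24 and 0 in Ler, at least 130.0-fold lower. Upstream of AT2G16510 by 67 bp (chromosome 2, 7161001 to 7161500), 565 reads in C24 stood against 2 in Ler, 319-fold lower (88.0 to 2644). The locus 119 bp downstream of the pseudogene AT1G35570 (chromosome 1, 13119001 to 13119500) had 392 reads in C24 and 1 in Ler, 443-fold lower (79.1 to 17548). NF-YC6 (AT5G50480; chromosome 5, 20557501 to 20558000, untranslated exon), which encodes a subunit of the NF-Y transcription factor, had 435 reads in C24 and 2 in Ler. Reads over coding sequence of AT2G39790 (chromosome 2, 16595001 to 16595500) numbered 458 in C24 and 2 in Ler, and those in an intron of AT3G52526 (chromosome 3, 19484501 to 19485000) 331 and 1. The locus 30 bp upstream of the long non-coding RNA gene AT5G07295 (chromosome 5, 19830001 to 19830500) had 493 reads in C24 and 2 in Ler, and an intergenic locus on chromosome 1 (8883501 to 8884000) had 738 and 5. At this intergenic locus 66.7% of the reads carried a mismatch.

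Of 42 measured miRNAs, 7 were at least 1.5-fold higher and 8 at least 1.5-fold lower in Ler. The largest differences were in miRNAs of the Brassicaceae or less conserved group, of which 5 of 13 were higher and 3 lower. MiR843 (AT3G48057; chromosome 3, 17742147 to 17742167) was 20.5 times the C24 level (12.4 to 36.2), and miR391 (AT5G60408; chromosome 5, 24293160 to 24293180) was 0.0866 of it (0.0789 to 0.0949). MiR400 stood at 7.71 (3.52 to 20.0), miR163 at 4.72 (2.52 to 9.60) and the abundant miR158a at 1.85 (1.84 to 1.87). MiR394a, which targets an F-box gene acting in the shoot meristem, was higher at 2.35 (1.48 to 3.84). Lower in Ler were miR164a (0.553), which targets NAC transcription factor genes, miR395a (0.533), of the sulfate starvation response, miR823 (0.393) and miR822 (0.650). Within the small RNA pathway group 2 of 4 were lower, miR173 at 0.619 (0.592 to 0.646) and miR162a at 0.626 (0.518 to 0.756), which direct the cleavage of trans-acting siRNA precursors and of DCL1 mRNA. In the leaf, organ and meristem group 1 of 9 was higher and 2 lower, in the nutrient and copper group 1 of 7 was higher and 1 lower, and none of 6 phase change and 3 auxin miRNAs passed. Relative to reads of 20 to 22 nt the counts were 11 higher and 2 lower, and miR173 (0.775), miR162a (0.785), miR822 (0.814), miR164a (0.693) and miR395a (0.668) no longer passed.

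Trans-acting siRNA genes produce phased 21-nt siRNAs, and 2 of the 8 were higher and 2 lower in Ler. TAS1B (chromosome 1, 18549204 to 18550042) was 4.70 times the C24 level (4.30 to 5.15) and TAS4 (chromosome 3, 9417551 to 9418705) 1.88 times (1.81 to 1.96). TAS1A (0.617) and TAS3A (0.604) were lower, while TAS1C (1.19), TAS2 (0.695), TAS3B (0.935) and TAS3C (0.632) did not pass the rule. TAS1A (0.694) and TAS3A (0.679) no longer passed relative to miRNA reads. Of 12 measured pentatricopeptide repeat (PPR) genes of the chromosome 1 clusters, known sources of secondary siRNAs, 2 were higher and 5 lower, with AT1G62860 at 0.0451. For 24-nt siRNAs with 1 kb on each side, 4 of 6 measured PPR genes were higher and none lower, and 3 trans-acting siRNA genes were higher and 3 lower. Over all genes compared, the median log2 ratio of Ler to C24 was −0.36 for 21-nt siRNAs (442 genes) and 0.29 for 24-nt siRNAs (9392 genes). The auxin receptor gene AFB3 was lower at 0.524, and 1 of the 3 measured receptor genes passed. For 24-nt siRNAs over genes with 1 kb on each side, 2 of 5 measured silencing genes were higher in Ler and 2 lower. The maintenance methyltransferase gene MET1 was at 41.6 (7.11 to 1677) and RDR2, which makes siRNA precursors double-stranded, at 14.5 (7.69 to 30.8). NRPE1, the largest subunit gene of RNA polymerase V, stood at 0.636 and DCL4 at 0.562, both lower, and DCL3 at 1.43 did not pass. AGO1, the main effector gene of the miRNA pathway and itself a miRNA target, was lower for 21-nt siRNAs at 0.608 (0.423 to 0.868). Of 5 measured genes known to be silenced or siRNA-associated, the histone demethylase gene IBM1 was higher at 4.87 (2.01 to 14.2), and FWA (0.980), SDC (0.696), QQS (0.731) and BNS (2.65, 0.917 to 9.33) did not pass. With miRNA reads as the base, NRPE1 (0.715) and AGO1 (0.684) no longer passed, while DCL3 (1.61) and BNS (2.98) were higher. On that base TAS3C for 24-nt siRNAs (0.730) and the PPR gene AT1G62914 for 21-nt siRNAs (0.723) were no longer called lower. Of the RPP4 and RPP5 resistance gene cluster, RPP4 was higher at 2.84 (1.67 to 5.03) and RLM3 was at 1.20, and none of 8 circadian clock genes reached the minimum of 40 reads in any comparison.

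The comparison of C24xLer with the mid-parent value asked whether this hybrid has the siRNAs that the mean of its parents predicts. It had less 24-nt siRNA than that in every annotated class, and 1380 loci were at least 1.5-fold lower while 126 were higher. Pseudogenes and transposon genes were at 0.743 of the mid-parent value, gene bodies at 0.765, the 1 kb upstream of genes at 0.842 and the 1 kb downstream at 0.858. Pericentromeres stood at 0.788 and chromosome arms at 0.822. In contrast, 17 of 42 miRNAs, 5 of 8 trans-acting siRNA genes and 8 of 12 PPR genes were higher. The 21-nt siRNAs rose across genes in general, with a median log2 ratio of 0.45 over the 442 genes compared. Part of these gene counts therefore follows from the higher 21-nt level of the library. Counting error gave 85.8 higher and 91.6 lower loci in simulated libraries. Relative to uniquely placed 24-nt reads, which takes out the overall 24-nt level, the split was 510 higher and 658 lower. In the same library the structural 24-nt to 21-nt ratio was 0.491 of the mid-parent ratio.

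Loci that differed between the parents were lower in C24xLer more often than the others, 1009 of 3675 (27.5%) against 371 of 3851 (9.63%), where the parental libraries both choose the loci and form the mid-parent value. The share was 23.3% of loci overlapping non-coding RNA genes, 20.4% of those overlapping pseudogenes or transposon genes, 18.5% of those overlapping protein-coding genes, 17.3% within 1 kb of a gene and 16.2% farther away. Downstream of AT1G47540 by 33 bp (chromosome 1, 17455001 to 17455500), 335 reads in Ler and 1 in C24 became 2 in C24xLer, 75.2-fold below the mid-parent value (20.7 to 624). A mismatch was present in 84.8% of the reads of this locus. Coding sequence of AT5G46825 (chromosome 5, 19002001 to 19002500) kept 1 read where Ler had 245 and C24 had 0, 0.00912 of the mid-parent value (0.000230 to 0.0513). A locus 41 bp upstream of SAC3A (AT2G39340; chromosome 2, 16423001 to 16423500) was at 0.00939 (0.000237 to 0.0528) and one 926 bp upstream of the long non-coding RNA gene AT5G03935 (chromosome 5, 8728001 to 8728500) at 0.0260 (0.0112 to 0.0516). At the SAC3A locus 61.6% of the reads carried a mismatch. At the edge of GP ALPHA 1 (AT2G26300; chromosome 2, 11196501 to 11197000), which encodes the alpha subunit of the heterotrimeric G protein, C24 was the high parent, and no read midpoint lay inside the gene. There 645 reads in C24 and 5 in Ler stood against 13 in C24xLer, 0.0396 of the mid-parent value (0.0210 to 0.0681). The locus beside AT1G35570 was at 0.0403 (0.0173 to 0.0801), and that 293 bp downstream of AT5G07855 (chromosome 5, 21155501 to 21156000), with 2096 reads in Ler, at 0.0617 (0.0467 to 0.0800). The locus at the edge of the non-coding RNA gene AT3G45638 (chromosome 3, 16755001 to 16755500) was at 0.0329 (0.0106 to 0.0774), with a mismatch in 95.1% of its reads.

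Higher than mid-parent by the widest margin was a locus at the edge of AT2G07750 (chromosome 2, 3576001 to 3576500), with 1 read in C24, 3 in Ler and 128 in C24xLer, a ratio of 69.3 (26.4 to 259). Of the reads at this locus over all libraries 92.8% carried a mismatch. An intergenic locus on chromosome 3 (15476001 to 15476500) was at 3.34 times the mid-parent value (3.07 to 3.65), and at 5.20 times without mismatched reads. The locus 613 bp upstream of AT3G42940 (chromosome 3, 15005501 to 15006000) was at 2.61 (1.99 to 3.43), a locus at the edge of AT2G25970 (chromosome 2, 11075501 to 11076500) at 2.55 (1.88 to 3.47) and an intron of the NAC transcription factor gene NAC093 (AT5G39690; chromosome 5, 15888501 to 15889000) at 2.02 (1.60 to 2.54). At the AT2G25970 and NAC093 loci 63.0% and 76.8% of the reads carried a mismatch. Further loci were coding sequence of AT5G28237 (chromosome 5, 10209001 to 10210000) at 1.89, the edge of AT2G13900 (chromosome 2, 5835001 to 5836000) at 1.77 and a locus 10 bp upstream of the beta-galactosidase gene BGAL8 (AT2G28470; chromosome 2, 12174001 to 12174500) at 1.65. Relative to miRNA reads NAC093 (1.49), AT5G28237 (1.36), AT2G13900 (1.35) and BGAL8 (1.24) no longer passed.

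MiRNAs higher in C24xLer came from 5 of the 6 groups. The Brassicaceae or less conserved group had 7 of 13, the leaf, organ and meristem group 4 of 9, the nutrient and copper group 3 of 7, the phase change group 2 of 6 and the auxin group 1 of 3, while none of the 4 small RNA pathway miRNAs passed. MiR159b stood at 2.74 times the mid-parent value (1.97 to 3.84) and miR159a at 2.15 (1.92 to 2.42), which target MYB transcription factor genes. MiR160a, which targets auxin response factor genes, was at 2.30 (1.80 to 2.94) and miR172a, which targets AP2-like genes of the phase change, at 1.85 (1.76 to 1.95). MiR396a, which targets growth-regulating factor genes, was at 1.87 (1.55 to 2.26), miR394a at 2.18 (1.62 to 2.93) and miR824 at 1.77 (1.56 to 2.01). MiR397a (1.98) and miR408 (1.85), which respond to copper supply, were higher together with miR823 (2.30), miR843 (2.02) and miR161.2 (1.68). Relative to reads of 20 to 22 nt the count was 6 higher and 2 lower, with miR159a (1.63), miR160a (1.75) and miR394a (1.59) among those above the threshold.

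Summed over the trans-acting siRNA genes, 21-nt siRNAs were at 1.60 times the mid-parent value in C24xLer (1.59 to 1.61). TAS1A (1.54), TAS1B (1.96), TAS1C (1.96), TAS2 (1.55) and TAS3A (1.75) were higher, TAS3B (1.26) and TAS3C (1.15) did not pass, and TAS4, which is triggered by miR828 and acts on MYB genes, was lower at 0.574 (0.552 to 0.597). Summed 21-nt siRNAs of the PPR genes were at 1.83 (1.76 to 1.90), with AT1G63080 at 2.18, AT1G63070 at 1.94 and AT1G63130 at 1.76. The median of the PPR list lay at the 98.7 percentile of 10000 random gene lists of like level, and that of the trans-acting siRNA list at the 77.5 percentile. AFB3 was higher at 1.58 (1.39 to 1.80), while AFB2 was at 1.45, so that 1 of 3 measured auxin receptor genes passed. Relative to miRNA reads, 2 of the 12 PPR genes and none of the trans-acting siRNA genes were higher. The median log2 ratio of 24-nt siRNAs over all 9392 genes compared was −0.31. List medians for 24-nt siRNAs lay at percentiles of 68.6 for PPR, 13.9 for trans-acting siRNA, 40.6 for silencing and 63.3 for silenced genes. For 24-nt siRNAs, TAS1B (0.589), TAS3B (0.199) and TAS4 (0.349) were lower among the 8 trans-acting siRNA genes and none was higher. No PPR gene passed in either direction, and NRPE1 was higher at 1.5 (1.09 to 2.06) among 5 silencing genes. The other silencing genes, DCL4 (1.45), RDR2 (0.803), MET1 (0.696) and DCL3 (0.672), did not pass, while 21-nt siRNAs of AGO1 were higher at 1.61 (1.24 to 2.1). BNS, a gene with siRNA-associated silencing, was at 2.27 (1.17 to 4.42), FWA at 1.04, QQS at 0.834, SDC at 0.802 and IBM1 at 0.730, and RPP4 was lower at 0.569 (0.334 to 0.930). The calls for NRPE1 (1.14), BNS (1.65, 0.851 to 3.21), AGO1 (1.22) and AFB3 (1.20) were lost relative to miRNA reads, and in that scaling 24-nt siRNAs of 7 trans-acting siRNA genes, 3 PPR genes, 3 silencing genes and 2 silenced genes were lower and none was higher.

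LerxC24 stood farther below the mid-parent value than C24xLer in 24-nt siRNA. Pseudogenes and transposon genes were at 0.614 of the mid-parent value, gene bodies at 0.638, the 1 kb upstream of genes at 0.697 and the 1 kb downstream at 0.706. Pericentromeres stood at 0.645 and chromosome arms at 0.679. At the level of loci, 2838 were at least 1.5-fold lower and 53 higher, against 92.6 and 84.5 from counting error alone. Meanwhile 13 of 42 miRNAs, 4 of 8 trans-acting siRNA genes and 4 of 12 PPR genes were higher, where the median log2 ratio of 21-nt siRNAs over the 442 genes compared was 0.35. Relative to uniquely placed 24-nt reads, which takes out the overall 24-nt level, the split was 626 higher and 797 lower. The structural 24-nt to 21-nt ratio of this library was 0.410 of the mid-parent ratio.

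Of the 3675 loci that differed between the parents 1682 (45.8%) were lower in LerxC24, and of the 3851 others 1156 (30%). Lower loci made up 44.1% of those overlapping non-coding RNA genes, 43.2% of those overlapping pseudogenes or transposon genes, 37.3% of those overlapping protein-coding genes, 34.9% within 1 kb of a gene and 35.6% farther away. The locus at AT3G45638 had 0 reads in LerxC24 against 339 in Ler, at least 54.7-fold below the mid-parent value, and that at the edge of AT3G28715 (chromosome 3, 10777501 to 10778000) had 0 against 316, at least 50.9-fold below it, with a mismatch in 89.2% of its reads. In an intron of the transcribed pseudogene AT3G46250 (chromosome 3, 16990501 to 16991000), 477 reads in C24 and 7 in Ler stood against 5 in LerxC24, 0.0190 of the mid-parent value (0.00613 to 0.0445). The locus beside AT1G35570 was at 0.0187 (0.00506 to 0.0481), that in AT5G46825 at 0.0169 (0.00204 to 0.0617), and an untranslated exon of AT1G11785 (chromosome 1, 3980001 to 3980500) at 0.0177 (0.00363 to 0.0521). The edge of AT1G32337 (chromosome 1, 11662001 to 11662500) was at 0.0145 (0.00175 to 0.0530) and that of AT4G12990 (chromosome 4, 7596001 to 7596500) at 0.0215 (0.00441 to 0.0634). The higher loci were again led by that beside AT2G07750, at 51.6 (19.5 to 194), and by the intergenic locus on chromosome 3, at 2.78 (2.54 to 3.04). The locus named for AT3G42940 was at 2.28, those for NAC093 at 2.046, for AT2G25970 at 1.99, for AT2G13900 at 1.82 and for the pseudogene AT5G34841 (chromosome 5, 13020001 to 13021500) at 1.80 (1.34 to 2.40). The locus 157 bp upstream of AT4G19620 (chromosome 4, 10683001 to 10683500) was at 1.5 (1.37 to 1.65), and at 1.27 relative to miRNA reads, where it no longer passed.

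MiR159b, at 2.96 times the mid-parent value (2.14 to 4.10), and miR843, at 2.5 (2.18 to 2.87), led the miRNAs of LerxC24, followed by miR159a at 2.23 (1.99 to 2.5). Within the nutrient and copper group 4 of 7 were higher, namely miR395b at 2.26 (1.42 to 3.61), miR395a at 1.74 (1.36 to 2.21), miR857 at 2.15 (1.46 to 3.17) and miR397a at 1.93 (1.66 to 2.24). MiR172a (1.75), miR396a (1.88), miR160a (1.72), miR823 (1.90) and miR400 (1.62) were higher as well. By group, 4 of 13 Brassicaceae or less conserved miRNAs, 3 of 9 of the leaf, organ and meristem group, 1 of 6 of the phase change group, 1 of 3 of the auxin group and none of 4 of the small RNA pathway group passed. Relative to reads of 20 to 22 nt, 5 were higher, among them miR159a (1.66) and miR843 (1.70), and 3 lower.

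The 21-nt siRNAs of the trans-acting siRNA genes summed to 1.49 times the mid-parent value in LerxC24 (1.48 to 1.5), and those of the PPR genes to 1.62 (1.56 to 1.69). TAS1A (1.52), TAS1B (1.98), TAS1C (1.66) and TAS3A (1.68) were higher, TAS4 was lower at 0.595 (0.573 to 0.618), and TAS2 (1.38), TAS3B (1.13) and TAS3C (1.28) did not pass. AT1G63080 was at 2.01 and AT1G63070 at 1.75, both higher, and AT1G63130 was at 1.49. List medians lay at the 82.1 percentile of random lists for the PPR genes and the 85.9 percentile for the trans-acting siRNA genes. Of the auxin receptor genes AFB3 (1.40) and AFB2 (1.36) did not pass. Relative to miRNA reads, 2 of the 12 PPR genes and 1 of the 8 trans-acting siRNA genes were higher. For 24-nt siRNAs the median log2 ratio over all 9392 genes compared was −0.59, so a typical gene lay near the 1.5-fold threshold. List medians for 24-nt siRNAs lay at percentiles of 63.3 for PPR, 15.8 for trans-acting siRNA, 69.5 for silencing and 12.9 for silenced genes. Against this general drop, 5 of 8 trans-acting siRNA genes and 2 of 6 PPR genes were lower for 24-nt siRNAs. So were DCL3, the gene of the enzyme that cuts 24-nt siRNAs, at 0.537 (0.416 to 0.688), and RPP4 at 0.502 (0.291 to 0.828). DCL4 (1.36), NRPE1 (0.923), RDR2 (0.732) and MET1 (0.645) did not pass, nor did 21-nt siRNAs of AGO1 (1.11). IBM1 (0.312, 0.108 to 0.743) and QQS (0.529, 0.329 to 0.824) were lower among 5 measured silenced genes, while FWA was at 1.04, SDC at 0.779 and BNS at 0.401. In the scaling to miRNA reads, 24-nt siRNAs were lower at 7 trans-acting siRNA genes, 4 PPR genes, 3 silencing genes and 4 silenced genes.

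Set against each other as crosses, the hybrids shared 1148 lower loci and 24 higher loci. Independent lists of the same sizes would share 520 and 1, and simulated hybrids at the mid-parent value shared 6.35 and 8.65. Part of the excess may come from the parents that both comparisons share. The overall 24-nt levels of the hybrids were 0.800 and 0.685 of mid-parent, which the simulated hybrids do not carry. Shared lower loci therefore follow in part from the lower level of both libraries. At loci that differed between the parents, where 0 is mid-parent and −1 the low parent, the median position was −0.34 in C24xLer (quartiles −0.65 and −0.04) and −0.55 in LerxC24 (−0.83 and −0.27). Loci higher in C24 were at medians of −0.24 and −0.48, and loci higher in Ler at −0.40 and −0.59. Over all 7526 loci the median log2 ratio to mid-parent was −0.27 in C24xLer and −0.58 in LerxC24. These medians moved to −0.71 and −0.83 relative to miRNA reads. Relative to uniquely placed 24-nt reads they were 0.03 and 0.00, and that scaling largely sets them near 0 by construction.

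**Figure D3:**
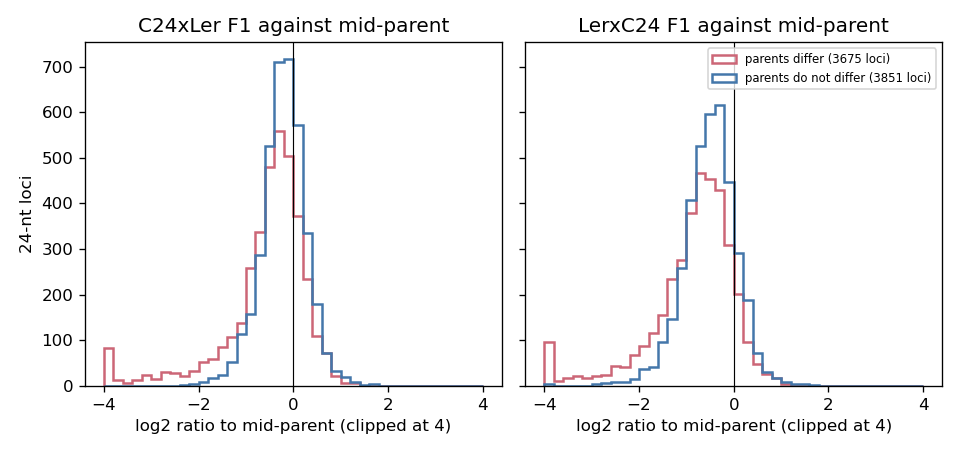
Number of 24-nt loci by log2 ratio of each hybrid to the mid-parent value, drawn for the 3675 loci that differed between the parents and the 3851 that did not. Ratios beyond 4 are drawn at 4; the medians of the 2 sets are −0.38 and −0.19 in C24xLer and −0.70 and −0.48 in LerxC24.

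The comparison of the reciprocal hybrids, whose nuclear genomes are alike, addressed the direction of the cross. LerxC24 had less 24-nt siRNA than C24xLer in every annotated class, between 0.814 and 0.834 of its level. By locus 392 were at least 2-fold lower in LerxC24 and 34 higher, against 64.1 and 58.8 from counting error alone. MiR394a was the only miRNA that passed, at 0.647 (0.466 to 0.893), and no trans-acting siRNA gene passed for 21-nt or 24-nt siRNAs. The split of loci was 56 higher and 192 lower relative to uniquely mapped reads, 63 and 192 relative to miRNA reads, and 101 and 134 relative to uniquely placed 24-nt reads. Structural fragments had 0.491 of the mid-parent 24-nt to 21-nt ratio in C24xLer and 0.410 in LerxC24.

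AT3G46250 was lower in LerxC24 at 0.145 of the C24xLer level (0.0440 to 0.374), the edge of AT2G09970 (chromosome 2, 3780501 to 3781000) at 0.225 (0.124 to 0.387) and the locus 561 bp upstream of AT2G28080 (chromosome 2, 11964001 to 11965000) at 0.300 (0.179 to 0.486). The locus downstream of UGT71B8 was at 0.332 (0.216 to 0.5), the locus 229 bp upstream of AT3G28430 (chromosome 3, 10663001 to 10664500) at 0.360 (0.233 to 0.544) and the edge of the long non-coding RNA gene AT3G02135 (chromosome 3, 2845501 to 2846000) at 0.401 (0.290 to 0.550). A locus 825 bp upstream of AT4G09670 (chromosome 4, 6110001 to 6110500) was at 0.436 (0.397 to 0.479). Mismatches were present in 97.8% of its reads, and without these the ratio was 0.824 and did not pass. Upstream of the pseudogene AT2G17460 by 674 bp (chromosome 2, 7580501 to 7581500) the ratio was 0.497 (0.448 to 0.550), and it no longer passed relative to uniquely mapped reads (0.557) or miRNA reads (0.562). Higher in LerxC24 were a locus 223 bp upstream of AT5G17440 (chromosome 5, 5749001 to 5749500), with 14 reads in C24xLer and 92 in LerxC24, at 6.09 (3.45 to 11.6), and the edge of TT5 (AT3G55120; chromosome 3, 20431501 to 20432000), the chalcone isomerase gene of flavonoid synthesis, at 2.66 (1.15 to 6.89). The other 6 named loci above equality stayed below 2-fold. They lay in AT1G52900 (1.69), AT3G06365 (1.62), the gamete fusion gene HAP2 (1.58) and AT4G10201 (1.65), and at the edges of the calcium sensor gene CBL2 (1.79) and AT2G04305 (1.49). At the HAP2 locus 94.9% of the reads carried a mismatch. For 24-nt siRNAs of the gene lists, NRPE1 was lower at 0.613, though not relative to miRNA reads (0.695, 0.470 to 1.02), and BNS was lower at 0.177 (0.0441 to 0.523). The PPR genes AT1G63400 for 24-nt siRNAs (0.599) and AT1G63230 for 21-nt siRNAs (0.623) were also lower, and neither passed relative to miRNA reads (0.678 and 0.705).

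Sites where the parental reads carried different bases gave the share of each parental genome among hybrid reads. Over 2736 nuclear sites, C24 bases made up 46.8% of reads in C24xLer (46.5 to 47.1) and 47.0% in LerxC24 (46.7 to 47.3), as the mean of sites where C24 and sites where Ler carried the reference base. The parental levels at these sites predicted 46.0%. Where C24 carried the reference base the shares were 55.8% and 56.6%, against 53.3% predicted, and where Ler did they were 37.9% and 37.3%, against 38.6%, on the other side of the prediction. At 24-nt loci higher in C24 the share was 74.5% and 75.0%, against 77.5% predicted, over 179 loci. At the 352 loci higher in Ler it was 28.5% and 29.6%, against 24% predicted, and at the 1065 loci that did not differ it was 52.8% and 53.9%, against 48.0%. The parental counts both choose these classes and give the prediction, so shares nearer to equality follow in part from that choice. Sites need at least 5 reads in each parent, so loci with almost none in 1 parent are left out. At the loci that did not differ, the shares were 58.0% and 59.0% against 50.3% where C24 carried the reference base. Where Ler did, they were 47.5% and 48.8% against 45.7%. The chloroplast held 1 such site, C74255T (the reference base, its position counted from 1 in the TAIR10.1 chloroplast sequence, then the other base), in psbN, a photosystem II gene. C24 had the reference base in 27 of 27 reads and Ler in 0 of 10. C24xLer had it in 32 of 32 reads (89.1% to 100%, exact binomial). LerxC24 had it in 0 of 27, where 3 counts would be 11.1% and the exact binomial upper limit is 12.8%. No mitochondrial site met the rule.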

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

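The test of 23- to 25-nt reads as a class was chosen after its result was seen. The lengths of miRNA reads were not among the planned tests, and the other tests in this part were chosen before.

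Loci that left the mid-parent value in opposite directions in the reciprocal hybrids were few. At 197 bp upstream of AT1G68570 (chromosome 1, 25745501 to 25746500), C24xLer was at 1.58 (1.10 to 2.26) and LerxC24 at 0.617 (0.373 to 0.987) of the mid-parent value, and the ratio of LerxC24 to C24xLer was 0.390. At 624 bp upstream of AT2G05510 (chromosome 2, 2014501 to 2015000) the values were 1.62 (1.10 to 2.36), 0.382 (0.194 to 0.698) and 0.236. A locus overlapping MIR8175 (chromosome 2, 3740501 to 3741000) went the other way, with 0.225 (0.0698 to 0.564), 1.75 (1.12 to 2.72) and a ratio of 7.78. With 1 library per hybrid these differences between crosses were not tested, and simulated hybrids at the mid-parent value gave 0.2 and 0.15 such loci on average in the respective directions.

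Reads of 18 to 30 nt that matched no position in the genome entered only the check below in which filtered and unmatched reads are added back. They held many reads of 24 nt. The 24-nt class made up 48.1% of them in C24, 52.4% in Ler, 39.8% in C24xLer and 35.6% in LerxC24, the same order of libraries as among matched reads.

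The lower 24-nt level of both hybrids is the pattern most in need of a second look. Other technical accounts were checked. With 23- to 25-nt reads together the level stayed at 0.850 and 0.782 of mid-parent in C24xLer and LerxC24, which speaks against misread lengths. Without miRNA, structural and organelle reads it was 0.840 and 0.742, which speaks against dilution. With filtered and unmatched reads of 18 to 30 nt added back it was 0.751 and 0.670. Filtered reads of these lengths numbered 573855 of 1285701 in C24xLer and 385284 of 1188773 in LerxC24. In C24 and Ler they numbered 178214 of 370683 and 321690 of 631059. The remaining filtered reads did not enter this check, so it speaks against the quality filter only for reads of 18 to 30 nt. A selection of shorter inserts in the hybrid libraries stays open and may account for the pattern in part or in full, since structural fragments had 0.491 and 0.410 of the mid-parent ratio of 24-nt to 21-nt reads. As a share of all structural fragments, those of 27 nt were at 0.370 and 0.0687 of the mid-parent share, those of 24 nt at 0.751 and 0.724 and those of 21 nt at 1.42 and 1.64. A lower production of 24-nt siRNA in hybrids also stays open, and these libraries cannot separate it from the preparation of each library and its lane.

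The hybrids lay further below mid-parent at loci that differed between the parents than at the others. The difference of the median log2 ratios was −0.19 in C24xLer and −0.22 in LerxC24, against −0.006 and −0.004 in libraries simulated with a uniform drop. These values do not exclude a uniform loss of 24-nt reads, as a selection of insert sizes gives. The parental libraries that choose these loci also form the mid-parent value, so an excess of reads in a single parental library puts the hybrids below it there, and the simulation holds counting error only. An effect of the hybrid genotype on loci that differ between parents is a candidate explanation and was not tested separately. A difference between the libraries or their lanes also stays open.

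The locus at the edge of AT2G07750 had 1 and 3 reads in the parents and 128 and 103 in the hybrids. A single overamplified molecule is argued against, since the most frequent sequence held 16.4% of the reads in C24xLer and 31.1% in LerxC24, among 31 and 23 distinct sequences. Whether the reads come from another copy of this sequence or from an organelle stays open, since 90.6% and 97.1% carried a mismatch to the placed position. Such an origin would not by itself explain the excess over the parents, from which the hybrids have their copies and organelles. Reads of 23 nt at the same locus numbered 69 and 63 in the hybrids and 0 and 2 in the parents. An siRNA cluster that forms in both hybrids is the biological account left open.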

How the results depend on the processing

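The scalings to structural fragments and to uniquely placed 24-nt reads and the 23- to 25-nt class, and the 21-nt alternatives for Ler against C24 and for the reciprocal hybrids, were chosen after the data were seen, and the other alternatives before. No paired analysis was possible because each group has 1 library, and for the same reason no library was left out. Where a value moved, the cause was not tested unless stated. Depth limits the gene lists: none of the 8 circadian clock genes reached the minimum of 40 pooled reads.

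In the order Ler against C24, C24xLer and LerxC24 against mid-parent, and LerxC24 against C24xLer, the 24-nt level moved as follows. It was 1.05, 0.769, 0.739 and 0.961 relative to uniquely mapped reads, 1.36, 0.593, 0.575 and 0.970 relative to listed miRNA reads, and 1.19, 0.764, 0.704 and 0.922 without structural and organelle RNA. With uniquely mapped reads alone in the size class it was 1.26, 0.811, 0.664 and 0.819, and with distinct sequences 1.07, 0.902, 0.839 and 0.931. Relative to structural fragments of 24 nt it was 1.31, 1.45, 0.829 and 0.573, so that C24xLer moved above mid-parent. The 21-nt level in the same order was 0.612, 1.22, 1.38 and 1.13 relative to uniquely mapped reads, 0.792, 0.974, 1.11 and 1.14 relative to miRNA reads, 0.695, 1.23, 1.34 and 1.09 without structural and organelle RNA, 0.804, 1.42, 1.34 and 0.938 with unique reads alone, 0.721, 1.33, 1.41 and 1.07 with distinct sequences, and 1.33, 1.21, 0.680 and 0.564 relative to structural fragments of 21 nt. It thus turned below mid-parent in C24xLer per miRNA and in LerxC24 per structural fragment, above C24 in Ler per structural fragment, and below C24xLer in LerxC24 per structural fragment and with unique reads alone.

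Counts of loci moved by over 1.5 times in these cases. Relative to uniquely mapped reads, 83 loci were higher in LerxC24 than mid-parent, and 56 were higher and 192 lower in LerxC24 than in C24xLer. Relative to miRNA reads 22 were higher and 3654 lower in C24xLer, 19 were higher in LerxC24, 63 and 192 differed between the reciprocals, and the median positions of C24xLer and LerxC24 were −0.63 and −0.70. Relative to uniquely placed 24-nt reads the splits were 510 and 658, 626 and 797, and 101 and 134, and the median positions of C24xLer and LerxC24 were −0.0633 and −0.0856. The median log2 ratios over all loci, −0.27 and −0.58 as reported, were 0.03 and 0.00 in the same scaling. Because this scaling takes out the overall 24-nt level, these values and the balance of the splits do not show whether that level fell. With at least 100 reads per window, where fewer loci are counted, 1232 were higher and 677 lower in Ler, 819 and 1746 were lower in C24xLer and LerxC24, and 9 were higher and 178 lower between the reciprocals. Higher loci numbered 96 in LerxC24 with 200-bp windows, 262 and 124 in C24xLer and LerxC24 with 23- and 24-nt reads, and 255 and 110 with 23- to 25-nt reads. At 2-fold in place of 1.5-fold, a stricter rule, 45 were higher and 828 lower in C24xLer, and 19 and 1722 in LerxC24.

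Relative to reads of 20 to 22 nt, 11 miRNAs were higher and 2 lower in Ler, 6 and 2 in C24xLer, and 5 and 3 in LerxC24. Counting reads that share the first 18 bases gave 3 miRNAs higher in LerxC24 than in C24xLer. The nuclear C24 share was 46.5% and 46.6% with at least 3 reads in each parent, and 48.4% and 49.3% with 24-nt reads alone, where the parental levels predicted 44.7%. That prediction also carries the difference in read lengths between the parental libraries. Of the values that answer a comparison, 65 stayed within their interval or within 1.5 times under an alternative, 83 moved and the 6 levels of length classes named above changed sides; the medians over all loci are not among these. Of values for single loci, genes, miRNAs, annotated classes and gene lists, 307 stayed and 89 moved, among them 23 of 37 named miRNAs relative to reads of 20 to 22 nt, and 12 of 64 named loci and 29 of 56 list members relative to miRNA reads.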

Other observations

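The values in this part were chosen after the data were seen, and no test of an explanation was run on them.

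Reads of miR825 (AT2G26211; chromosome 2, 11159774 to 11159794) separated the parental alleles at A6G, the reference base, its position from 1 at the 5' end of the mature sequence, and the other base. C24 had the other base in 100 of 100 reads and Ler in 0 of 55, where 3 counts would be 5.45% and the exact binomial upper limit is 6.49%. C24xLer had it in 34 of 84 reads, 40.5% (29.9 to 51.7), and LerxC24 in 31 of 88, 35.2% (25.3 to 46.1), so reads of both alleles were present in both hybrids. Because miRNAs were counted by identity to the reference sequence, miR825 reads of C24 were not counted in the miRNA comparisons.

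Trans-acting siRNA genes also gave 24-nt reads inside the gene, and at TAS1A, TAS1B and TAS3A the parental difference in these was opposite to that in the 21-nt class. TAS1A was at 0.617 of the C24 level in Ler for 21-nt siRNAs but at 3.14 (2.99 to 3.29) for 24-nt siRNAs, and TAS1B at 4.70 for 21-nt but 0.530 (0.419 to 0.667) for 24-nt siRNAs. TAS3A was at 0.604 for 21-nt and 1.52 (1.40 to 1.66) for 24-nt siRNAs. Over all genome-matched reads the 24-nt to 21-nt ratio of Ler was 1.72 times that of C24. The contrasts at TAS1A and TAS3A run the same way as this shift of the library, and that at TAS1B runs against it. How far the shift accounts for the contrasts at TAS1A and TAS3A was not tested. TAS4 was above C24 in both classes, at 1.88 and 6.33 (3.53 to 12.3). Among the auxin receptor genes, 24-nt siRNAs of AFB1 with its flanks were at 4.42 (2.81 to 7.25) in Ler, and in the hybrids at 0.840 and 0.749 of mid-parent, neither past the threshold, but lower relative to miRNA reads at 0.604 (0.431 to 0.835) and 0.610 (0.433 to 0.847). Those of AFB3 were at 0.607 and 0.450 of mid-parent, of which LerxC24 passed, and relative to miRNA reads both passed at 0.449 and 0.377.

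Small RNAs of 21 nt downstream of protein-coding genes were at 1.86 and 1.63 times the mid-parent value in C24xLer and LerxC24, the highest of the annotated classes in both by counts of reads, and those in gene bodies at 1.22 and 1.14. By distinct sequences they were at 1.40 and 1.37 downstream and 1.297 and 1.43 in gene bodies, and downstream was the highest class in neither hybrid. Fewer reads of 24 nt stood in these same classes, at 0.858 and 0.706 downstream and 0.765 and 0.638 in gene bodies.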
